A study of Homo sapiens with 10 samples.

How the data were processed

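Polyadenylated RNA of EndoC-βH1 cells, an insulin-producing human beta cell line, was sequenced on an Illumina HiSeq instrument from 5 preparations that received a control siRNA and 5 that received an siRNA against SRp55, the splicing factor encoded by SRSF6. Per the series' design text the preparations were independent. Groups and replicate numbers were taken from the sample labels, and no library was left out. Per the submitters' processing notes, reads were aligned with TopHat to GRCh37 (hg19). The TopHat version, the program that assigned reads to transcripts, the gene annotation release and any use of strand are not given in the sources used here.

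Each deposited file lists the same 155130 transcripts of 26346 genes with exon structure, an estimated number of reads that is usually fractional, and an RPKM value. In the files, the deposited RPKM equals the reads divided by transcript length and by one total per library, and that total exceeds the reads assigned to transcripts. The reads assigned per library ranged from 61.9 to 189.8 M (M, 10 to the power 6), and the total used for the RPKM from 79.5 to 210.0 M. Assigned reads made up 82.1% ± 6.82 of that total in control libraries and 87.0% ± 7.24 in SRp55 siRNA libraries (SD, n = 5), so RPKM values carry this difference. The 13 mitochondrial genes were listed with 0 reads in every library. Because reads and RPKM share a text field, the values were analysed by the route fixed for RPKM, and the estimated reads served as an alternative. The route fixed for counts in a checkable column, edgeR on summed reads, was not run.

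Gene values were sums of transcript RPKM. Gene symbols and transcript biotypes came from GENCODE 44, matched by Ensembl ID, which gave a symbol to 95.0% of genes and a biotype to 92.4% of transcripts. Coordinates are those of the files (GRCh37) unless GRCh38 is named. Genes with a mean of at least 0.5 RPKM over all libraries were tested with limma 3.58.1 (R 4.3.3) on log2(RPKM + 0.5) with the trend and robust options, no block, and Benjamini-Hochberg adjustment over all genes tested at 0.05. On this scale the fold change of genes with low RPKM is understated. As the scaling moved the median tested gene by 0.11 on the log2 scale, against 0.01 with median-of-ratios size factors, log2 fold changes are given relative to the median tested gene, SRp55 siRNA over control siRNA. Adjusted p-values test the change as deposited.

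Gene lists were fixed before the data were examined, as were the tests and the rule for named genes. There were 19: beta cell identity and transcription factors, insulin secretion and exocytosis, apoptosis, JNK signalling, the unfolded protein response, SR proteins and close relatives, hnRNP and tissue splicing regulators, nonsense-mediated decay factors, p53 targets, cell cycle and proliferation, cholesterol biosynthesis, nuclear genes of oxidative phosphorylation, glycolysis, interferon response, ribosomal proteins, monogenic diabetes genes, other islet endocrine cell markers, acinar and duct cell markers, and mesenchymal, endothelial and immune cell markers. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation as an alternative and fry as another set test.

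Transcript usage was the percent of a gene's summed RPKM held by one transcript. Transcripts with a mean of at least 0.5 RPKM and 5% usage entered limma's diffSplice F test on log2(RPKM + 0.5). A gene was called at an adjusted p under 0.05 with a shift of at least 10 percentage points in some transcript. Lists among called genes and the overlap with changed expression were tested with Fisher's exact test. The shares of protein-coding gene expression in transcripts annotated nonsense_mediated_decay and retained_intron were compared by exact two-sided permutation of the 10 library values, whose smallest possible p is 0.00794.

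Named genes were SRSF6, the 6 largest rises and the 6 largest falls among called genes with a symbol, at least 2 RPKM in the higher group and no overlap between groups, and up to 3 called members of each list with the smallest adjusted p. For usage they were the 8 largest shifts among called genes with a mean of at least 2 RPKM and no overlap of the top transcript between groups, and called members of the apoptosis, JNK, insulin secretion, SR protein, hnRNP, beta cell identity and monogenic diabetes lists. INS, PDX1, GLIS3, BCL2L11, BAX, MAPK8 and MAPK9 were named whatever their p. Readthrough genes, pseudogenes and small RNA genes were skipped among the largest changes.

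Whether equal replicate numbers pair the libraries was checked from the correlation of each library's deviations from its group mean over tested genes. It lay between 0.13 and 0.41 for equal numbers and reached at most 0.12 for different numbers, and each of the 10 libraries correlated best with its own number. The numbers were therefore treated as pairs in an alternative fit with a replicate block, whose value is given where it changes the call of a named gene and, for lists, as counts of members. Within a group, libraries correlated at 0.967 to 0.983 across genes, and no more than 0.274% of transcripts above 0 had identical reads in any 2 libraries, so each library counted as 1 replicate.

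The gene fit was tested on simulated libraries with the real mean and spread of each transcript. Transcripts were drawn independently of each other and libraries were not paired, so the rates may differ in the real data. Of 67 genes changed 2-fold, 58.2% were recovered, against 5.97% of 67 changed 1.5-fold and 90.8% of 65 changed 4-fold, and 4 of 106 calls were false. The diffSplice step recovered 63.6% of 99 genes whose usage was moved by 40 points and 21.2% of 99 moved by 20 points, but 26 of its 110 calls were false (23.6%). With arcsine square-root percentages 5 of 98 calls were false (5.10%).

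The alternatives were the replicate block, leaving out each library, other pseudocounts, filters and thresholds, median-of-ratios scaling, limma without its trend and robust options, estimated set correlation, and usage tested on arcsine square-root percentages. Chosen after seeing the data were limma's voom on summed reads, gene reads over 1 fixed length per gene in the same limma fit as the RPKM, removal of each library's GC and length trend, and a restriction to genes without a 6-base word in the 3' UTR. Words of 7 bases were scanned in the 3' UTR and coding sequence of the most abundant coding transcript of 12493 genes (GENCODE 44), with length and GC content as covariates. Figures and the scan used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.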

Results

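Transcript and gene expression was measured by polyA RNA sequencing in EndoC-βH1 cells, a clonal human beta cell line that makes insulin, after transfection with a control siRNA or with an siRNA against SRp55, a serine/arginine-rich splicing factor encoded by SRSF6. Each group held 5 independent preparations. Reads assigned to transcripts came to 115 M ± 36.5 in control and 128 M ± 36.1 in SRp55 siRNA libraries (SD, n = 5), with a lowest value of 61.9 M. Per the series title, the study asked which splicing events and beta cell genes depend on SRp55.

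The siRNA target was read first. SRSF6 (ENSG00000124193.10, chromosome 20, 42086568 to 42092245) was at 98.2 ± 3.24 RPKM in control libraries and 24.9 ± 3.78 RPKM in SRp55 siRNA libraries (SD, n = 5), which left 25.3% of the control mean. Every SRp55 siRNA library, at 21.0 to 31.1 RPKM, lay below every control library, at 92.4 to 100.0 RPKM. The log2 fold change was -2.08 (SE 0.11, limma adjusted p = 2.0e-05), and the exact permutation test of the 10 values gave p = 0.00794, the smallest it can give. Both SRSF6 transcripts fell. The coding transcript ENST00000244020.3 went from 65.4 ± 2.07 to 18.2 ± 3.22 RPKM, and the transcript annotated for nonsense-mediated decay, ENST00000483871.2, from 32.8 ± 1.89 to 6.69 ± 0.926 RPKM (SD, n = 5).

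**Figure D1:**
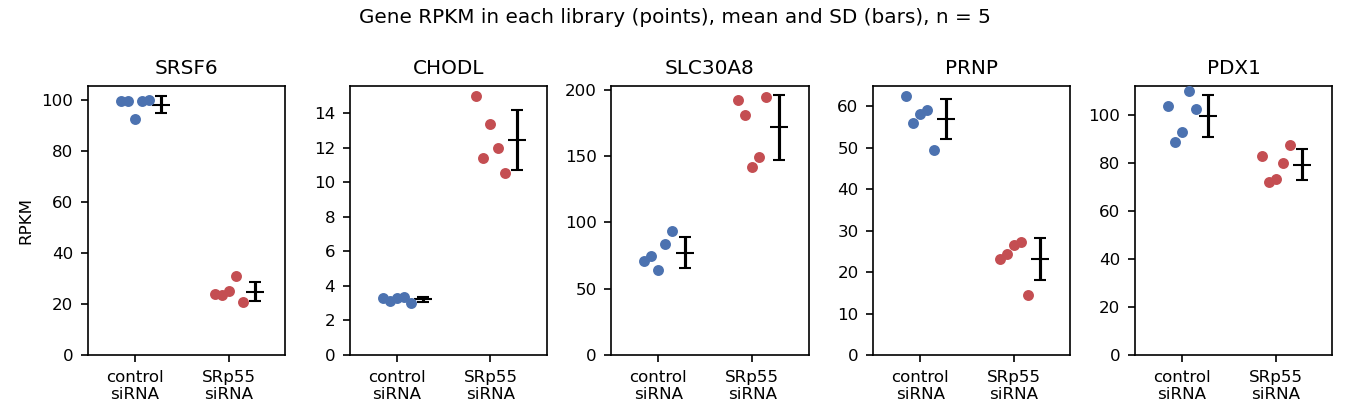
RPKM of 5 named genes, on vertical axes that start at 0, in each of the 5 control siRNA libraries (blue) and 5 SRp55 siRNA libraries (red), with the mean and SD as bars. SRSF6 and PRNP are lower and CHODL and SLC30A8 higher in every SRp55 siRNA library than in every control library, and PDX1 does not overlap between groups but did not pass the adjusted threshold.

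Beyond SRSF6, the largest falls were in AQP3, an aquaglyceroporin, PRNP, the prion protein, MRPS27, a protein of the small mitochondrial ribosomal subunit, FYCO1, an adaptor in autophagosome transport, and SLC10A3, a membrane protein of the bile acid transporter family. AQP3 fell from 17.9 ± 5.25 to 6.39 ± 1.62 RPKM (log2 fold change -1.52), and PRNP from 56.9 ± 4.86 to 23.1 ± 5.05 RPKM (-1.42). MRPS27, at 24.1 ± 2.88 RPKM in control libraries, had a log2 fold change of -1.36, which is 2.56-fold lower relative to the median tested gene. SLC10A3 fell from 5.39 ± 0.462 to 2.06 ± 0.306 RPKM (-1.31). The largest rises were in MARCHF3, a membrane-bound ubiquitin ligase, CHODL, a lectin-like membrane protein, SULF1, an extracellular sulfatase of heparan sulfate, CHD7, a chromatin remodeller, DPYSL3, a protein of axon growth, and PCLAF, which binds PCNA in DNA replication. CHODL rose from 3.22 ± 0.144 to 12.5 ± 1.74 RPKM (log2 fold change 1.68) and CHD7 from 57.1 ± 26.6 to 164 ± 23.8 RPKM (1.52; SD, n = 5 throughout).

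MARCHF3 had the largest rise on RPKM sums, from 1.95 ± 1.33 to 11.1 ± 1.22 RPKM (log2 fold change 2.27, SE 0.28, adjusted p = 0.0024), but on summed reads its change was 1.30, below CHODL (1.87) and SULF1 (1.32). The changes of CHD7 and DPYSL3 were also smaller on summed reads, 0.94 and 0.75. SULF1 rose 3.02-fold to 6.24 ± 3.00 RPKM, DPYSL3 to 2.35 ± 1.81 RPKM (1.31) and PCLAF to 103 ± 21.7 RPKM (1.24; SD, n = 5). FYCO1, at 8.68 ± 4.08 RPKM in control libraries and 3.07 ± 0.261 in SRp55 siRNA libraries, was called on RPKM (log2 fold change -1.34, adjusted p = 0.036) but not on summed reads (-0.14, adjusted p = 0.36). The adjusted p of the other falls lay between 0.00074 for SLC10A3 and 0.0068 for AQP3, and that of the other rises between 2.0e-05 for CHODL and 0.037 for DPYSL3. The annotated 3' UTRs of AQP3, MRPS27 and SLC10A3 hold the word CAGGCTT and those of PRNP and SLC10A3 the word AGGCTTA. These words went with lower expression over all genes (closing section). Genes given with CAGGCTT were not searched for a separate AGGCTTA. FYCO1, which also fell, holds neither word nor their core AGGCTT. Among the rises, SULF1 holds both words, joined as CAGGCTTA, as SLC10A3 does, and DPYSL3 holds CAGGCTT. CHD7 holds the core AGGCTT alone, and MARCHF3, CHODL and PCLAF hold none of these.

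In all, 684 of 13630 tested genes changed, 513 higher and 171 lower (limma, adjusted p under 0.05), and 2986 had an unadjusted p under 0.05. With median-of-ratios scaling 933 genes were called, 433 higher and 500 lower. That scaling centres each library on its median ratio, so the balance of higher and lower calls depends on the centring chosen. No called gene changed direction between the scalings, but only 522 of the 684 were also called with median-of-ratios scaling. On summed reads, where 2327 genes were called, 638 of the 684 were called in the same direction. Of the called genes 605 did not overlap between groups, and 7.92% of all tested genes did not, against 0.794% by chance. The replicate block raised the count to 1784, and leaving out 1 library gave from 259 genes, without control replicate 2, to 1083, without control replicate 4.

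**Figure D2:**
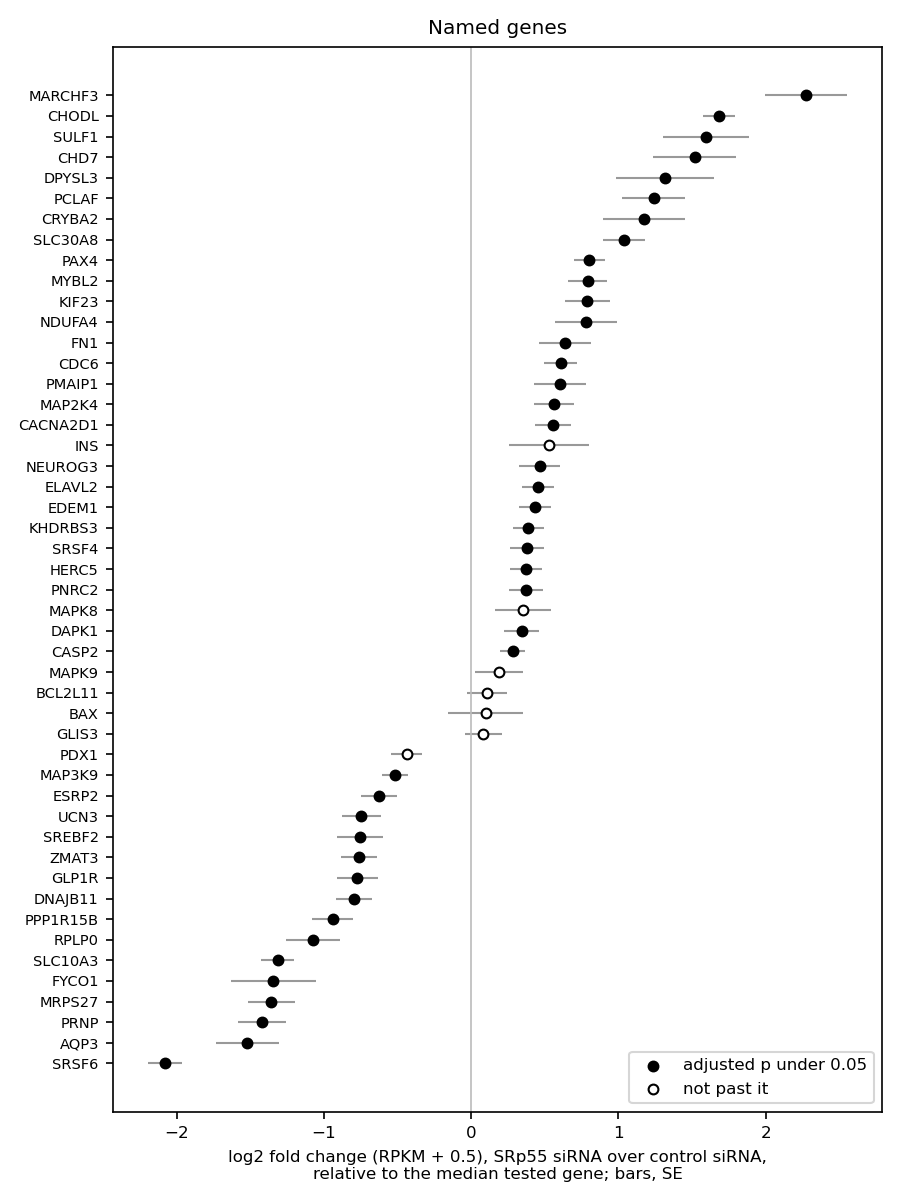
Log2 fold change of each named gene on the horizontal axis, SRp55 siRNA over control siRNA and relative to the median tested gene, with its SE as bars and n = 5 per group. Filled points passed the adjusted p of 0.05, and open points, among them INS at 0.53 and PDX1 at -0.44, did not.

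Cell cycle genes were higher together after SRp55 knockdown. Of 46 measured members 13 rose, none fell and 33 did not pass. Adjusted over the list alone, 30 rose and none fell. Adjusted over all genes, as for the 13, 29 rose with the replicate block, 11 with median-of-ratios scaling and 22 on summed reads, and none fell. MYBL2, a transcription factor of the G2/M genes, rose from 15.2 ± 2.42 to 28.8 ± 3.81 RPKM (log2 fold change 0.79, adjusted p = 0.0055), KIF23, a kinesin of cytokinesis, from 11.6 ± 2.36 to 21.7 ± 1.76 RPKM (0.79, adjusted p = 0.00998) and CDC6, which licenses replication origins, from 25.1 ± 3.45 to 41.3 ± 3.73 RPKM (0.61, adjusted p = 0.0080; SD, n = 5). The other 10 were CENPE, E2F1, FOXM1, GINS2, KIF20A, MCM4, MCM5, MKI67, TK1 and UBE2C.

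The list's median log2 fold change was 0.36, with 41 of 46 members above the median tested gene, and camera called it at the preset correlation (adjusted p = 2.5e-10). With an estimated correlation it was not called (camera p = 0.053 unadjusted, 0.98 adjusted over the lists). By fry, which asks whether the members move one way on balance, the adjusted p was 0.013 as deposited. It was 0.039 with median-of-ratios scaling. As deposited, the direction by fry was up for every list. The mean standardized value of the list was -0.50 ± 0.50 in control libraries and 0.50 ± 0.24 in SRp55 siRNA libraries (SD, n = 5), higher in 5 of 5 pairs (exact permutation p = 0.00794, the smallest it can give). The paired permutation test over the 5 pairs did not pass and cannot (p = 0.0625, the smallest it can give). Control replicate 1 was lowest, at -1.40, and without it the list's median log2 fold change was 0.24. No other list was called by camera on RPKM with all libraries.

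**Figure D3:**
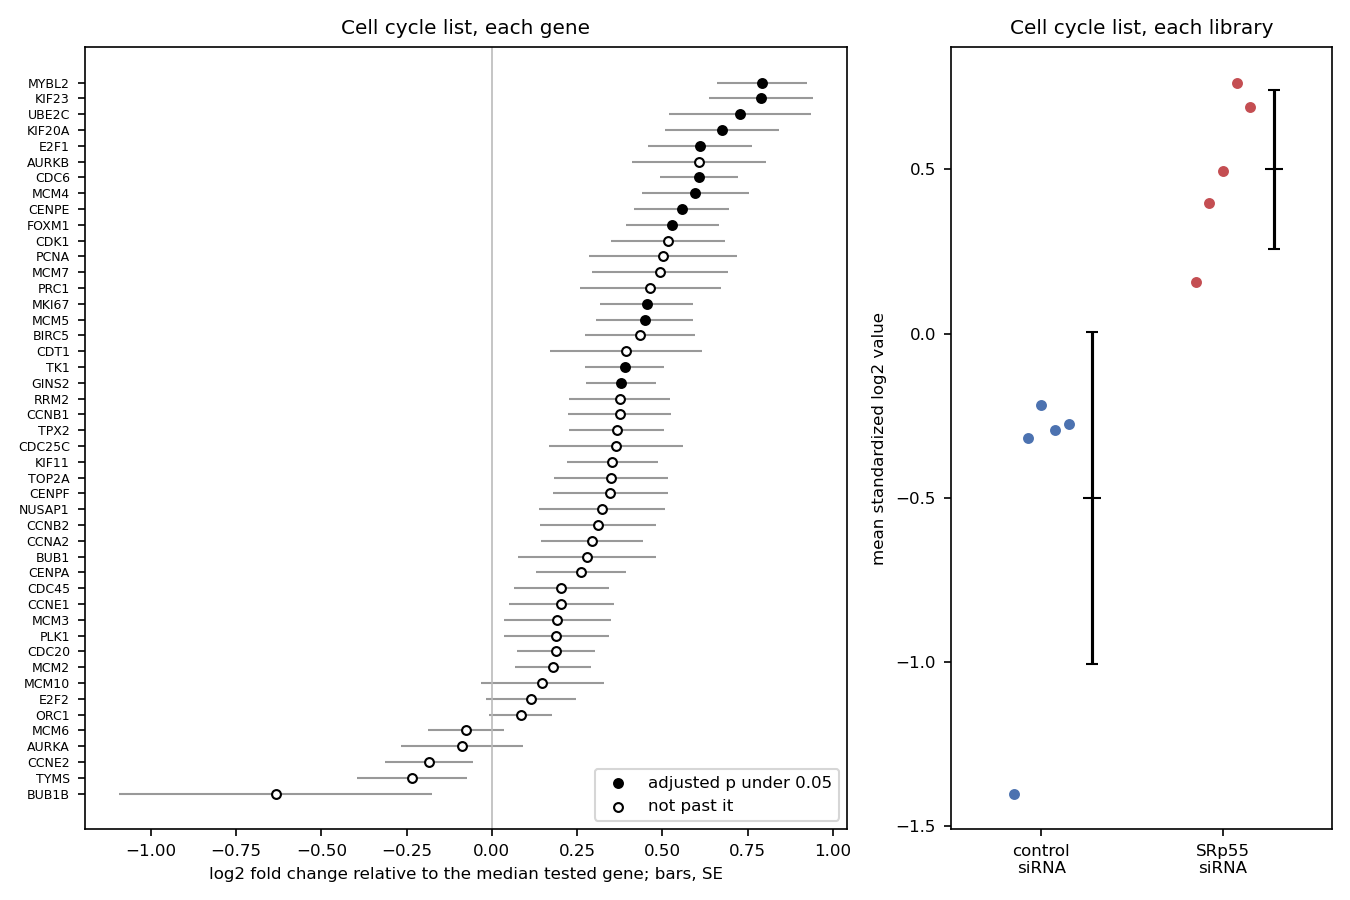
Left, log2 fold change relative to the median tested gene for each of the 46 cell cycle genes, with SE bars, filled where the adjusted p was under 0.05. Right, the mean standardized log2 value of the list in each control siRNA (blue) and SRp55 siRNA (red) library, with mean and SD; control replicate 1 sits at -1.40 and all 5 SRp55 siRNA libraries above all controls.

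Beta cell genes moved in both directions. Of 39 beta cell identity genes SLC30A8 rose, UCN3 and GLP1R fell and 36 did not pass (3 rose and 2 fell adjusted over the list alone). SLC30A8, the zinc transporter of insulin granules, rose from 77.3 ± 11.4 to 172 ± 24.6 RPKM (log2 fold change 1.04, adjusted p = 0.0025). UCN3, a peptide of mature beta cells, fell from 19.7 ± 2.61 to 12.5 ± 1.86 RPKM (-0.74, adjusted p = 0.022), and GLP1R, the incretin receptor, from 4.46 ± 0.780 to 2.62 ± 0.423 RPKM (-0.77, adjusted p = 0.025; SD, n = 5). With the replicate block 5 genes of the list rose and 5 fell, and on summed reads 3 rose and 9 fell.

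INS, at 6597 ± 3464 RPKM in control and 9520 ± 1414 RPKM in SRp55 siRNA libraries, was not called (log2 fold change 0.53, SE 0.27, adjusted p = 0.20). Control replicate 4, at 12705 RPKM, stood apart from the other controls, at 4237 to 5840 RPKM. Without it INS was called higher (log2 fold change 0.75, adjusted p = 0.0095). With all libraries INS was not called with the replicate block (adjusted p = 0.078), with median-of-ratios scaling (0.17) or on summed reads (0.082). PDX1, the beta cell homeobox factor, was at 99.8 ± 8.63 and 79.4 ± 6.49 RPKM (log2 fold change -0.44, SE 0.10, adjusted p = 0.10), lower in 5 of 5 pairs, and passed with the replicate block (adjusted p = 0.028), with median-of-ratios scaling (0.035) and on summed reads (0.0098). GLIS3, a transcription factor linked to diabetes, was at 18.4 ± 2.23 and 21.1 ± 2.96 RPKM (log2 fold change 0.08, adjusted p = 0.40; SD, n = 5).

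Among 29 monogenic diabetes genes PAX4 and NEUROG3 rose, PPP1R15B fell and 26 did not pass (4 rose and 3 fell adjusted over the list alone, 6 and 3 with the replicate block, 4 and 5 on summed reads). PAX4, a developmental repressor, was low, at 0.451 ± 0.0940 and 1.29 ± 0.140 RPKM (log2 fold change 0.80, adjusted p = 0.0024), and NEUROG3, the endocrine progenitor factor, was at 3.22 ± 0.585 and 5.01 ± 0.609 RPKM (0.47, adjusted p = 0.040; SD, n = 5). Of 62 insulin secretion genes CACNA2D1, a calcium channel subunit, rose (log2 fold change 0.56, adjusted p = 0.015), none fell and 61 did not pass, with the same 1 rise adjusted over the list alone. Of these 62 genes 7 rose and 1 fell with the replicate block, 1 rose and 3 fell with median-of-ratios scaling, and 4 rose and 7 fell on summed reads.

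In the apoptosis list 3 of 51 genes rose, none fell and 48 did not pass (4 rose adjusted over the list alone). PMAIP1, the BH3-only protein NOXA, rose from 45.9 ± 3.57 to 77.9 ± 24.1 RPKM (log2 fold change 0.60, adjusted p = 0.042). CASP2 (0.28, adjusted p = 0.029) and DAPK1 (0.34, adjusted p = 0.049) rose less, and neither passed with median-of-ratios scaling (adjusted p = 0.16 and 0.068), under which 2 genes of the list rose and 3 fell. The counts were 6 and 1 with the replicate block and 5 and 6 on summed reads. The pro-apoptotic genes BAX, at 106 ± 42.8 and 118 ± 31.3 RPKM, and BCL2L11, at 13.8 ± 2.40 and 16.0 ± 2.00 RPKM (SD, n = 5), had adjusted p of 0.68 and 0.39.

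Of 48 JNK signalling genes MAP2K4, a kinase that activates JNK, rose from 19.5 ± 2.85 to 31.3 ± 4.49 RPKM (log2 fold change 0.56, adjusted p = 0.023), and MAP3K9, an upstream kinase, fell from 5.96 ± 0.303 to 4.38 ± 0.227 RPKM (-0.51, adjusted p = 0.027; SD, n = 5). The other 46 did not pass, and 1 rose and 1 fell both when adjusted over the list alone and with median-of-ratios scaling. However, 8 rose and 2 fell with the replicate block, and 8 rose and 3 fell on summed reads. MAPK8, which encodes JNK1, was at 67.0 ± 19.2 and 90.7 ± 14.7 RPKM (log2 fold change 0.35, adjusted p = 0.20). MAPK8 passed with the replicate block (adjusted p = 0.044), on summed reads (0.039) and without control replicate 4 (0.047), but not with median-of-ratios scaling (0.13). MAPK9 was at 22.2 ± 5.83 and 27.0 ± 3.63 RPKM (0.19, adjusted p = 0.32; SD, n = 5). MAPK9 passed on summed reads (adjusted p = 0.010) but not with the replicate block (0.20) or median-of-ratios scaling (0.35).

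Among 48 genes of the unfolded protein response EDEM1 and CHAC1 rose, PPP1R15B and DNAJB11 fell and 44 did not pass (6 rose and 2 fell adjusted over the list alone, 9 and 4 with the replicate block, 6 and 7 on summed reads). PPP1R15B, a phosphatase subunit that relieves eIF2α phosphorylation, fell from a mean of 25.5 to 14.2 RPKM (log2 fold change -0.94, SE 0.14, adjusted p = 0.00998) and DNAJB11, an endoplasmic reticulum chaperone, from 64.8 ± 4.95 to 40.3 ± 5.87 RPKM (-0.80, adjusted p = 0.011; SD, n = 5). EDEM1, of glycoprotein degradation, had a log2 fold change of 0.44 (adjusted p = 0.020).

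Few splicing regulators passed the threshold, as did few of all tested genes (684 of 13630). Of 36 SR proteins and relatives, SRSF6 left aside, SRSF4 rose from 27.7 ± 1.42 to 39.3 ± 6.07 RPKM (log2 fold change 0.38, adjusted p = 0.037) and no longer passed with median-of-ratios scaling (adjusted p = 0.078), while none fell and 35 did not pass (2 rose with the replicate block). Of 60 hnRNP and tissue regulators ELAVL2 (0.45, adjusted p = 0.017), KHDRBS3 (0.39, adjusted p = 0.027) and HNRNPA3 rose, ESRP2, an epithelial regulator, fell (-0.63, adjusted p = 0.038) and 56 did not pass, in equal numbers adjusted over the list alone. In this list 6 rose and 2 fell with the replicate block, 3 rose and 4 fell with median-of-ratios scaling, and 6 rose and 6 fell on summed reads. Of 21 nonsense-mediated decay factors PNRC2 rose (0.37, adjusted p = 0.038) and 20 did not pass, and on summed reads 2 fell.

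In the remaining pathway lists few genes passed the threshold. Of 26 p53 targets PMAIP1 rose and ZMAT3 fell (log2 fold change -0.76, adjusted p = 0.015), and of 26 cholesterol genes SREBF2, the sterol-responsive transcription factor, fell (-0.76, adjusted p = 0.040). NDUFA4 rose among 76 oxidative phosphorylation genes (0.78, adjusted p = 0.037) but not with the replicate block (adjusted p = 0.064). That list had a camera adjusted p of 0.40 with all libraries, 0.0011 without control replicate 4 and 0.030 on summed reads, each at the preset correlation. HERC5 rose among 26 interferon genes (0.37, adjusted p = 0.031) but not with median-of-ratios scaling (adjusted p = 0.070), and none of 23 glycolysis genes passed. RPLP0 fell among 76 ribosomal protein genes (-1.07, adjusted p = 0.017). Its level is uncertain because ribosomal protein genes have many pseudogenes. The ribosomal list had a camera adjusted p of 0.83, and of 0.0045 without control replicate 4. With an estimated correlation and all libraries the adjusted p of both lists was 0.98. With the replicate block 4 p53 targets rose and 1 fell, and 1 and 2 cholesterol genes, 1 and 1 oxidative phosphorylation genes, 2 and 1 interferon genes, and 1 and 2 ribosomal genes did so. On summed reads these counts were 3 and 2, 0 and 1, 2 and 0, 2 and 1, and 0 and 3, and 1 glycolysis gene fell.

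Few markers of other cell types passed the threshold. Of 11 measured islet endocrine markers CRYBA2, a crystallin of endocrine cells, rose from 146 ± 59.4 to 338 ± 79.2 RPKM (log2 fold change 1.17, adjusted p = 0.027; SD, n = 5), and the list's median was -0.16, with 3 rises under the replicate block. None of 5 measured acinar and duct markers passed. Of 4 measured mesenchymal, endothelial and immune markers FN1, fibronectin, rose from 8.08 ± 2.00 to 13.7 ± 2.37 RPKM (0.64, adjusted p = 0.037; SD, n = 5).

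Of the 40 named genes past the threshold beside SRSF6, 20 passed under every alternative in which they were tested and none changed sign. The calls of CASP2, CRYBA2, DAPK1, DPYSL3, EDEM1, ESRP2, FN1, FYCO1, GLP1R, HERC5, KHDRBS3, MAP2K4, MAP3K9, NDUFA4, NEUROG3, PMAIP1, PNRC2, SREBF2, SRSF4 and UCN3 were lost under at least 1, most often with a library left out, at adjusted p up to 0.36. MRPS27, DNAJB11 and ESRP2 overlap PTCD2, TBCCD1 and NFATC3 on the other strand, and ESRP2, at a mean of 9.84 RPKM, is less abundant than NFATC3, at 25.4 RPKM, so their levels are less certain.

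Among the list members given above, the 3' UTR holds CAGGCTT in GLP1R, MAP3K9, ESRP2, ZMAT3 and SREBF2, which fell, and in EDEM1, which rose. Among members without CAGGCTT, AGGCTTA is held by DNAJB11 and RPLP0, which fell. The core AGGCTT alone is held by PPP1R15B, which fell, and by SLC30A8, MAP2K4, ELAVL2, CDC6 and HERC5, which rose. UCN3, which fell, holds none of these, nor do CACNA2D1, CASP2, PMAIP1, DAPK1, SRSF4, KHDRBS3, PNRC2, MYBL2, KIF23, NDUFA4, PAX4, NEUROG3, CRYBA2 and FN1, which rose.

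Transcript usage was compared to ask which isoforms change with SRp55. In TCF3, a basic helix-loop-helix transcription factor, the transcript ENST00000592395.1, annotated for nonsense-mediated decay (chromosome 19, 1609291 to 1615797), held 77.2% ± 4.69 of the gene's RPKM in control and 6.62% ± 6.78 in SRp55 siRNA libraries. In SYNE4, a nuclear envelope protein, the retained-intron transcript ENST00000505054.2 (chromosome 19, 36494209 to 36499512) went from 71.8% ± 5.17 to 4.13% ± 1.86. In DGCR8, the partner of DROSHA in microRNA processing, the coding transcript ENST00000351989.3 (chromosome 22, 20067755 to 20099394) went from 32.9% ± 6.90 to a listed 0 in all 5 SRp55 siRNA libraries, while ENST00000383024.2 went from 1.64% ± 2.57 to 32.8% ± 13.5 (SD, n = 5). In BNIP3L, a mitophagy receptor of the apoptosis list, the coding transcript ENST00000380629.2 (chromosome 8, 26240414 to 26270645) went from 49.1% ± 8.62 to 25.8% ± 3.40 (SD, n = 5).

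Adjusted p from diffSplice was 3.1e-14 for DGCR8, 2.0e-08 for SYNE4, 2.1e-06 for BNIP3L and 1.1e-05 for TCF3. The other named shifts were in MARCHF3, whose short coding transcript ENST00000515241.1 went from 12.4% ± 14.9 to 83.7% ± 7.47, in NUDT12, a nucleotide hydrolase, whose ENST00000507423.1 went from 5.80% ± 2.77 to 38.3% ± 14.1, in SDK1, a cell adhesion protein, with a retained-intron transcript at 13.2% ± 5.75 and 49.3% ± 27.1, and in USP11, a deubiquitinase, whose ENST00000377107.2 went from 84.5% ± 3.30 to 59.7% ± 14.3 (SD, n = 5). Their adjusted p lay between 0.0038 for NUDT12 and 0.040 for SDK1 and MARCHF3, and SDK1 was not called with the replicate block (adjusted p = 0.057). Tested on transcript reads, TCF3, MARCHF3, SDK1 and USP11 were not called (adjusted p = 0.30, 0.63, 0.23 and 0.22), and DGCR8 and SYNE4 alone among the 8 were called under every alternative. DGCR8 and BNIP3L overlap TRMT2A and PNMA2 on the other strand, and with the use of strand unknown their shares are less certain.

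**Figure D4:**
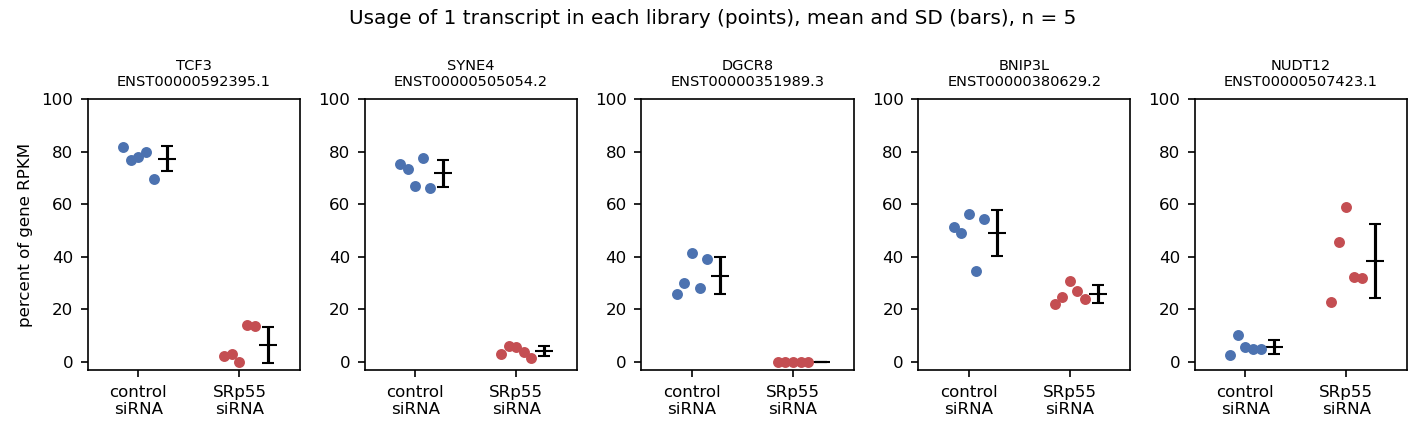
Percent of the gene's RPKM held by 1 transcript of TCF3, SYNE4, DGCR8, BNIP3L and NUDT12 in each control siRNA (blue) and SRp55 siRNA (red) library, with the mean and SD as bars. Groups do not overlap in any of the 5 panels, and the DGCR8 transcript is listed at 0 in every SRp55 siRNA library.

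Among 9915 genes with at least 2 measured transcripts, 34 were called for changed usage (diffSplice, adjusted p under 0.05 and a shift of at least 10 points), and 810 had an unadjusted p under 0.05. The count is not firm, since 30 of 100 splits of the same libraries, the real one included, gave as many, and the median of the other splits was 24. In simulated libraries 26 of 9693 genes with unchanged usage were called, against 34 of 9915 here. The 23.6% of simulated calls that were false depends on how many genes were changed there, so it cannot be applied to the 34. With arcsine square-root percentages 4 genes were called, DGCR8, SYNE4, TCF3 and SYDE1, the last of which was chosen after its values were seen. In SYDE1, at a mean of 1.89 RPKM, 1 transcript went from 0.183% ± 0.410 to 91.1% ± 8.25 of the gene (SD, n = 5).

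Usage was not called for BAX, BCL2L11, MAPK8, MAPK9, GLIS3 or INS. The largest shifts there were 5.68 points for BAX (adjusted p = 0.97), 4.41 for BCL2L11 (0.90), -8.10 for MAPK8 (0.87), -16.7 for MAPK9 (1.00), 4.40 for GLIS3 (1.00) and -2.31 for INS (1.00). For MAPK9, the transcript held 84.0% of the gene in control replicate 4 and 0 to 14.9% in the other controls. SRSF6 moved by 6.32 points (adjusted p = 0.79). Because a 20-point shift was recovered in 21.2% of simulated genes, shifts of that size would mostly be missed with 5 libraries per group.

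No list was enriched among genes with changed usage (Fisher's exact test, one-sided, adjusted p of 1 for all 17 lists with at least 5 tested members). BNIP3L was the only called gene of the apoptosis list, NDUFS1 of oxidative phosphorylation and RPL15 of ribosomal proteins, and the other 14 lists had none. NDUFS1 and RPL15 were named after their values were seen. Of the 34 genes 8 also changed in expression (MARCHF3, PRNP, MATN2, CYYR1, SPATS2, PPP2R1B, DPY19L2 and DMWD), with an odds ratio of 6.26 (95% interval 2.43 to 14.3, two-sided Fisher's exact p = 0.00015). It was 2.23 (0.977 to 4.76, Fisher's exact p = 0.039) with expression tested on summed reads, where 11 of 1759 changed genes were called for usage, against 8 of 471, and no longer passed without control replicate 2 (3.25, p = 0.14) or 3 (4.29, p = 0.088). With the replicate block CYYR1 was not called for usage (adjusted p = 0.12), and 23 of the 34 genes were.

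Transcripts annotated as retained introns held 8.42% ± 0.640 of the RPKM of protein-coding genes in control and 9.03% ± 0.228 in SRp55 siRNA libraries (SD, n = 5), higher in 4 of 5 pairs. The difference of 0.606 points did not pass (exact permutation p = 0.0556). With each library left out in turn, it passed only without control replicate 4 (0.806 points, exact permutation p = 0.00794). Transcripts annotated for nonsense-mediated decay held 5.72% ± 0.297 and 6.001% ± 0.229 (SD, n = 5), a difference of 0.285 points (exact permutation p = 0.11). With each library left out in turn, this difference passed only without control replicate 1 (0.391 points, exact permutation p = 0.040). The Benjamini-Hochberg adjusted p of both tests with all libraries was 0.11, while the p-values with a library left out were not adjusted. The paired permutation test over the 5 pairs gave p = 0.19 for both types. On shares of summed reads the exact permutation test gave p = 0.11 for both.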

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

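The tests in this part were planned or written down before their results were seen, except the share of higher calls under median-of-ratios scaling, the look at the split with the most genes and the cell cycle score with a library left out, which replaced a permutation test that was at its floor.

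In 14 of 136 groups of 5 libraries a single library lay far from the other 4, where chance gives about 6.8. Among controls these were SRSF6 in replicate 3 (92.4 RPKM, others 99.5 to 100.0), MAP2K4 in replicate 5 (14.5, others 20.2 to 21.2), KIF23 in replicate 1 (7.44, others 12.3 to 13.1), and in replicate 4 NDUFA4 (12.1, others 5.62 to 6.39), INS (12705, others 4237 to 5840) and MAPK9 (32.4, others 17.7 to 21.4). Among SRp55 siRNA libraries they were PCLAF and PNRC2 in replicate 5 (66.2 RPKM, others 107 to 123, and 77.9, others 101 to 105), and BAX and MAPK9 in replicate 1 (173 RPKM, others 95.6 to 112, and 33.3, others 24.4 to 26.4). In usage they were BAX ENST00000293288.8 in control replicate 1 (12.7%, others 3.60 to 5.17%) and MAPK9 ENST00000397072.3 in control replicate 4 (84.0%, others 0 to 14.9%). SRp55 siRNA replicate 4 had 189.8 M assigned reads (others 94.7 to 119.8 M), and control replicate 1 a cell cycle score of -1.40 (others -0.32 to -0.22). Control replicate 4 accounts for 4 of the 14 and control replicate 1 for 3.

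Of 100 splits of the 10 libraries drawn from 126, the real one included, 2 gave as many changed genes as the real 684. That share is under 0.05, but these splits ignore the pairs. The highest other count, 1207, came from a split that puts control replicate 4 with SRp55 siRNA replicates 1 to 4 and so parts 3 of the 5 pairs. A count above the real one points to a structure of the libraries. On that side assigned reads were 85.0 to 96.5% of the total used for the RPKM, on the other 74.2 to 87.1%, and with median-of-ratios scaling that split called 0 genes by limma. With that scaling 1 of 100 splits, the real one with 933 genes, gave as many, and the highest other gave 2. The share of calls that were higher was 46.4% with median-of-ratios scaling and 78.0% after each library's GC and length trend was removed, against 75% as deposited. Among the 11 splits drawn that part all 5 pairs, the highest other count was 1, but 5 pairs cannot give a p under 0.0625 by paired permutation. Chance is therefore not excluded at 0.05 when the pairs are kept.

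For changed usage 30 of 100 splits gave as many genes as the real 34 (highest other 286, and 35 among those that part all 5 pairs), and with arcsine percentages 15 of 100 gave as many as the real 4 (highest other 19), so chance is not excluded for either count. The split with 286 genes parts 1 pair, and so large a count points to a structure of the libraries. For lists called by camera 87 of 100 splits gave as many as the real 1 (highest other 5), and chance is not excluded. For genes changed in both expression and usage 2 of 100 splits gave as many as the real 8 (highest other 15), but only 2 other splits called 8 or more genes for expression, so this count leaves open whether chance made the overlap.

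Cell cycle genes were higher after SRp55 knockdown, with a median log2 fold change of 0.36 over 46 genes (camera p = 0.053 unadjusted and 0.98 adjusted, with an estimated correlation). Among 100 splits 1, the real one, moved that median as far (highest other 0.34), although 87 of 100 splits called at least 1 list. The rank of the real split argues against chance only with the pairs ignored, since 5 pairs cannot give a p under 0.0625 by paired permutation. After removal of each library's GC and length trend the median was 0.35, which argues against such bias as the whole source. Control replicate 1 carries part of the difference, as the median was 0.24 without it, but is not the sole source, since the lowest difference in score with a library left out, the one without it, was 0.775 (SE 0.124). The score was higher in 5 of 5 pairs, so an effect of the siRNA treatment may account for it, but with 1 siRNA per group an effect of SRp55 loss cannot be separated from one of the siRNA itself.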

How the results depend on the processing

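Voom on reads, a fixed gene length, the GC and length trend, median-of-ratios with block and the restriction to genes without AGGCTT were chosen after seeing the data, and the cause was not tested unless named. The fall of SRSF6 passed under every alternative run. The count of changed genes, 684, was 1784 with the replicate block, 2327 with voom on summed reads and 4878 with voom and block. It was 1566 with median-of-ratios and block, 1817 with reads over a fixed gene length and 63 with an absolute log2 fold change of at least 1 (fewer by construction). Among genes without AGGCTT in the 3' UTR, where fewer genes were tested, it was 317, 283 higher and 34 lower. Lower calls were thus lost in larger proportion than higher calls, which numbered 171 and 513 in the main fit. Leaving out 1 library gave 259 to 1083 genes: 330, 259, 306, 1083 and 268 without control replicates 1 to 5, and 460, 319, 297, 315 and 805 without SRp55 siRNA replicates 1 to 5. Lists called were 1 to 3 with a library left out (3 without control replicate 4), 2 with voom and 0 with an estimated correlation. There the cell cycle median stays 0.36 by construction, and its camera p was 0.053 unadjusted and 0.98 adjusted. That median was 0.24 (without control replicate 1) to 0.43 with a library left out. Genes with changed usage, 34, were 67 with lower and 14 with higher transcript minimums, 4 with arcsine percentages, 16 with voom on transcript reads, and 24 to 52 with 1 library left out (52 without control replicate 1 or 4). The odds ratio of the overlap ranged from 3.25 (without control replicate 2) to 16.0 with a library left out, and was 4.29 without control replicate 3. With a library left out the difference in share ranged from 0.202 to 0.391 points for nonsense-mediated decay transcripts and from 0.373 to 0.806 for retained introns, and by summed reads it was 0.198 and 0.392. Of the tests of named genes under alternatives, 692 kept their side of the threshold in expression, 144 lost and 8 gained a call, and in usage 259 kept it and 36 lost a call. For lists other than cell cycle 357 kept it and 3 gained a call. No call past the threshold reversed. Short of it, BAX and some list medians changed sign with a library left out, among them those of beta cell identity and of acinar and duct markers. Higher genes outnumbered lower as deposited (513 to 171) but not with median-of-ratios (433 to 500) or summed reads (1121 to 1206). With 58.2% of 2-fold changes recovered in simulated libraries, smaller changes are often missed.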

Other observations

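The test of the 8-base word in the SRSF6 transcript was chosen after the word scan was seen, and that of a fixed gene length after the overlap on summed reads was seen, while the scan, the removal of GC and length trends, the usage test and its shuffled words were written down before.

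Genes with particular short words in the 3' UTR were lower after SRp55 siRNA. In a scan of all 7-base words over 12493 genes, 21 words went with lower expression after Bonferroni adjustment and none with higher, and 16 of the 21 share 6 bases with CAGGCTTA. In the linear model of limma's fold changes over genes the strongest was AGGCTTA, with a log2 difference of -0.15 (SE 0.01, Bonferroni-adjusted p = 1.3e-37, 942 genes), followed by CAGGCTT (-0.11, adjusted p = 3.4e-35, 1645 genes). In the same model on summed reads, TTACAAA and ATTACAA did go with higher expression (Bonferroni-adjusted p = 0.0075 and 0.019). Of 159 lower genes with a 3' UTR, among them AQP3, PRNP, MRPS27, SLC10A3, SREBF2 and GLP1R, 114 hold AGGCTT (71.7%, against 32.5% of all genes, Fisher's exact p = 3.9e-24), and of 483 higher genes 127 do (26.3%). For medians each gene was put in 1 class only, so these classes are smaller than the gene sets of the scan. The median log2 fold change was -0.14 (95% interval -0.20 to -0.10) for the 281 genes with CAGGCTTA and -0.08 for 1364 others with CAGGCTT. It was -0.10 for 510 genes with AGGCTTA but not CAGGCTT, -0.03 for 1900 with AGGCTT alone and 0.04 for 8438 with none. Unlike the scan, Fisher's exact test and these medians were not adjusted for 3' UTR length or GC content. The scan, the test and the interval all treat genes as independent.

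A candidate explanation is seed pairing of the SRp55 siRNA, whose guide would then lower transcripts other than SRSF6, and it predicts that the SRSF6 transcript itself holds the word. CAGGCTTA occurs in its coding exon 3 (chromosome 20, 43459844 to 43459851, GRCh38), with 0.0663 occurrences expected by chance over the whole transcript of 4353 bases. The median of -0.14 for genes with the 8-base word, not adjusted for length or GC content, lies below that for the core alone. The effect of AGGCTTA was smaller in coding sequence (-0.07) than in the 3' UTR (-0.15), just under the 0.5 ratio set beforehand, while for CAGGCTT it was -0.07 against -0.11, above that ratio. After removal of each library's GC and length trend the Bonferroni-adjusted p of AGGCTTA was 1.0e-38, which argues against that bias as the source. As this hypothesis was found and tested on the same libraries, and the siRNA and the loss of SRp55 coincide in the design, a role of SRp55 in transcripts with the word stays open and untested.

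Seed pairing was also tested on usage, since it could move transcripts of 1 gene against each other. In 1571 genes with transcripts both with and without CAGGCTT or AGGCTTA anywhere in their sequence, those with it lost usage in 1016 (64.7%). That value passed the test set beforehand (binomial p = 1.4e-31), but 100 shuffled words gave a median of 62.4% and up to 67.3%, so it does not separate this word from others and leaves the question open. Longer transcripts may lose usage whatever word they carry. The usage-weighted mean transcript length was 1877 bases in control and 1790 bases in SRp55 siRNA libraries (exact permutation p = 0.0794, lower in 4 of 5 pairs).

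Genes with changed usage were also more often changed in expression (odds ratio 6.26, 8 genes), and 1 explanation tested is that a gene's RPKM sum moves when its reads are assigned to a transcript of another length, as in MARCHF3, where a transcript of 719 bases took over. In the same limma fit on reads over 1 fixed length per gene the odds ratio was 2.33 (9 genes, Fisher's exact p = 0.039). It met the bound set beforehand, but changed genes also rose from 471 to 1333, so whether RPKM sums account for the overlap cannot be told apart from the larger number of calls. With the fixed length 5 of the 8 genes were called for expression, and SPATS2, DPY19L2 and DMWD, chosen after their values were seen, were not (adjusted p = 0.058, 0.068 and 0.66). No biological explanation was tested.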
